A study of Homo sapiens with 28 samples.

How the data were processed

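The series holds 28 RNA-seq libraries from human breast cancer cell models, 1 library in each of 28 groups. Per the labels' protocols, the cells spent 48 hours in medium with charcoal-stripped serum, which removes steroids, and then received vehicle, 10 nM estradiol (E2), 10 nM R5020 or both for 12 hours. Total RNA was extracted with a Qiagen kit, polyadenylated RNA was selected and libraries were made with a NEBNext kit. The submitters' processing notes name TopHat, Cufflinks and Cuffdiff and the build hg19. Their versions and options are not given in the sources used here.

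The deposited tables, 1 for each of 7 models, give per row a list of RefSeq accessions and 4 expression values, which are taken as FPKM (fragments normalized to transcript length and library size) because Cuffdiff, named in the authors' processing notes, reports that unit. Per the file headers, the authors also deposited a ratio (fold) of each hormone over vehicle and its log2 value. Dividing each treated value by its deposited fold gave 3 vehicle values per row, and the deposited vehicle column equalled their mean within 0.1% in 100% of rows of every table. Each hormone was therefore taken to have been set against vehicle in a run of its own, 3 runs per table. Over the rows used, the vehicle values of the runs differed by a median SD of 0.0191 to 0.0611 log2 units, and their median shift against the E2 run reached -0.113 in ZR75. Rows with discordant vehicle values had been left out by then, as described below, so these figures do not cover all deposited rows.

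The tables hold 433 to 3248 rows and are selections of genes. Among rows whose ID occurs once, 3 in ZR75, 2 in T47D siControl and 1 in T47D siFOXA1 had a deposited log2 fold under 1 in all 3 contrasts, and 0 in each of the other tables. A gene that is not listed has no value, and nothing follows about whether it changed. The siFOXA1 table carries 1 accession per row and its deposited name refers to a further selection whose rule is not given in the sources used here, so counts are not compared across tables. IDs listed more than once (120 in T47D, 76 in ZR75, 68 in PR-deficient T47D, 45 in MCF7, 36 in T47D siControl, 44 in T47D siNF1C and 18 in T47D siFOXA1) were left out. In 6 tables each such ID listed every combination of its values in the 3 hormone columns, as did 17 of the 18 in T47D siFOXA1, so a row need not hold values of 1 locus. Rows whose 3 vehicle values (plus 0.5) lay more than 1.5 times apart were left out as well, a choice made after the data were examined. This left 2463 rows in T47D, 1322 in ZR75, 425 in PR-deficient T47D, 1407 in MCF7, 1136 in T47D siControl, 782 in T47D siNF1C and 367 in T47D siFOXA1.

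Library depth cannot be read from these values. Cufflinks shares fragments between transcripts, so low FPKM are not whole multiples of the worth of 1 fragment, and the selected rows do not sum to a library. Intervals that need counts are therefore not given. Over the rows used, median FPKM lay between 2.70 and 4.33 in the 24 libraries of 6 tables and between 0.702 and 0.892 in the 4 libraries of PR-deficient T47D.

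Gene symbols came from the RefSeq gene table of assembly GRCh38.p14 by accession. Between 97.2% and 98.7% of the accessions of a table matched. Because that assembly differs from hg19, no coordinates are printed. Rows that join several genes stayed in all counts of rows but were not used for named genes or lists, and a gene with several rows was taken from the row with the highest mean FPKM.

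Ratios were computed as log2 of (FPKM + 0.5) in one library over (FPKM + 0.5) in the other, from the 4 deposited columns. The pseudocount pulls ratios of weakly expressed genes toward 0. A row was counted as changed when the ratio reached 2-fold (1 log2 unit) and at least 1 of both libraries had an FPKM of 1 or more. With 1 library per group there is no replicate error, no test was run and no p-value is given. Every count and ratio compares libraries, and the spread between cultures of 1 condition is unknown. E2+R5020 was also set against E2, and the relation between R5020 over vehicle and E2+R5020 over E2 shares no library. Models were compared over genes listed in both tables, beside n1 × n2 / N, the overlap of independent lists. Correlations are across genes, which are not independent replicates.

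Gene lists (22) and the rule for naming genes were fixed before the data were examined. The rule took, in T47D, the 8 highest and 8 lowest ratios of each hormone against vehicle, and 4 and 4 in each other model and for E2+R5020 against E2. It also took ESR1, PGR, NFIC and FOXA1, up to 4 members with the largest ratios of each list described, and, between models, the 6 strongest shared genes and the 6 furthest apart. Small RNA families and uncharacterised loci were not named. The median of a list with at least 5 listed members was placed among 10000 random lists of the same size from the same table, matched on mean FPKM in 10 bins. That percentile describes these libraries and is relative to other selected genes. The step was tested on simulated data: with an assumed noise of 0.1 log2 SD added to the T47D vehicle values (1854 rows), 88% of 50 genes changed 2.5-fold, 100% of 50 changed 4-fold and 0% of 50 changed 1.5-fold were called for E2 against vehicle. That noise is smaller than the SD of 0.55 between the E2 ratios of T47D and T47D siControl, so the simulation checks the computation and gives no error rate for these libraries.

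Alternatives fixed before the data were examined were pseudocounts of 0.1 and 1, no floor, a floor of FPKM 5, centring of ratios on their median, and random lists matched in 5 bins. Alternatives chosen after seeing the data were the vehicle value of each run, all rows with an ID listed once, all deposited rows, the authors' log2 folds, and leaving out rows that join a small RNA. The work used Python 3.11, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.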

Results

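RNA was sequenced from 7 breast cancer cell models, each under 4 conditions: vehicle, 10 nM E2, 10 nM R5020 (promegestone, a synthetic progestin) or both hormones, for 12 hours. T47D and ZR75 are luminal lines labelled positive for the estrogen and progesterone receptors (ER and PR). PR-deficient T47D cells and MCF7 cells, another luminal line, are labelled ER-positive and PR-deficient. T47D cells were also treated with a control siRNA (siControl), with siNF1C or with siFOXA1. The series title sets the genomic effects of ER and PR beside each other, and the design allows each hormone to be compared with vehicle and R5020 to be compared in the absence and presence of E2. Each group has 1 library, so no value below carries a replicate error and no difference was tested. Levels are FPKM and changes are log2 ratios. "Higher" and "lower" counts refer to listed rows past 2-fold. The tables list selected genes only, so percentages and medians describe those genes and not the transcriptome, and a gene's absence from a table says nothing about its change.

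The gene of the progesterone receptor, PGR, was listed in the tables of parental T47D cells and of the T47D cells given an siRNA. In T47D it went from an FPKM of 22.0 with vehicle to 72.1 with E2, 2.61 with R5020 and 13.1 with both hormones. In T47D siControl the corresponding FPKM values were 12.4, 65.3, 3.87 and 11.2. PGR was 2.35 log2 units above vehicle with E2 and -1.56 with R5020 in siControl cells, and -0.14 with both hormones. PGR had no row in the ZR75, PR-deficient T47D or MCF7 tables, so its level there could not be used to check the PR-deficient labels. ESR1, which encodes ER alpha, had no row in any of the 7 tables.

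The siRNA targets were available in part. The label siNF1C does not spell out its target. NFIC, the gene of nuclear factor I/C and the nearest gene name, had a vehicle FPKM of 13.5 in T47D siNF1C and 20.8 in T47D siControl, a ratio of 0.651. The ratio was 0.608 with E2, 0.616 with R5020 and 0.741 with both hormones. The tables were normalized separately, so these ratios set levels side by side across normalizations. NFIC itself was higher with R5020 than with vehicle, by 1.14 in T47D, 0.99 in siControl and 0.91 in siNF1C. FOXA1, a pioneer transcription factor of luminal cells, had no row in the siRNA tables, so the siFOXA1 label could not be checked. In T47D, FOXA1 was 211 with vehicle, 157 with E2, 136 with R5020 and 95.3 with both hormones.

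In T47D, the highest E2 ratios included known estrogen targets. CXCL12, a chemokine gene, went from an FPKM of 4.39 to 215 (5.46), and TFF1, a secreted trefoil peptide gene, from 6.08 to 102 (3.96). SUSD3 (4.32), OLFM1 (4.26), STC2 (3.84), FLT4 (3.69), IFITM10 (3.59) and CLPSL2 (3.41) completed the highest 8. The lowest ratios were at IL1R1, the interleukin 1 receptor gene (-2.48), SPINK8 (-2.26), EFNB2 (-2.25), NDRG1 (-2.18), NTN4 (-2.06), FILNC1 (-2.05), the pseudogene NCOR1P1 (-1.97, uncertain because of its parent gene) and LINC01845 (-1.82). Of 30 listed estrogen response genes, 27 were higher and 0 lower, with a median of 1.77 (percentile 100 among random lists). Of 27 listed DNA replication and G1/S genes 21 were higher, with a median of 1.31 (percentile 99.99), led by CDC6 (2.07), MCM10 (from 1.11 to 5.95 FPKM), CDC45 (1.90) and MCM2 (1.85). Ribosome biogenesis genes were higher in 6 of 7 listed (median 1.15, and 0.99 after centring, percentile 95.8), among them NOP16 (1.75) and RRS1 (1.54). None of 14 listed mitosis genes reached 2-fold (0 higher, 0 lower), although all 14 lay above 0, with a median of 0.50. Of 1990 rows past the floor, 414 were higher and 178 lower. Centring on the median of the listed rows (0.15) changed that split to 312 higher and 284 lower.

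With R5020 alone other genes had the highest ratios. ARMC12 went from 1.11 to 67.1 FPKM (5.39) and RBP2, a retinol-binding protein gene, from 0.680 to 43.3 (5.21). AZGP1 (4.61), TRNP1 (4.39), TMEM63C (4.28), HSD11B2, which encodes the enzyme that inactivates cortisol (4.09), ATAD2 (3.99) and SEPTIN4 (3.89) followed. The lowest were L3MBTL3 (-3.09), IL1R1 (-2.96), TGFB2 (-2.95), ROBO2 (-2.87), PGR (-2.86), LINC01947 (-2.81), TWIST1 (-2.70) and MECOM (-2.55). The row of FKBP5, a steroid-induced chaperone gene, joins a second locus and lies outside the naming rule. It is added after its values were seen: the authors' deposited table gives log2 folds of 0.55 with E2, 5.30 with R5020 and 5.34 with both.

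All 27 listed replication and G1/S genes were higher (median 2.87, percentile 100), with CDC6 at 3.56, MCM10 at 3.55, GINS2 at 3.50 and CDC45 at 3.48. Of 14 listed mitosis genes, 13 were higher (percentile of the median 97.6), the other being BUB1 at 0.92, chosen after its value was seen. They were led by AURKB (2.26), CDK1 (1.97) and MKI67 (1.77). Among 17 listed progestin response genes, 12 were higher and 0 lower (median 1.55, percentile 99.8), including STAT5A (3.29), NDRG1 (2.60) and ATP1B1 (2.56). Fatty acid and lipid genes were higher in 6 of 9 listed, with ACSL1 at 1.75, FASN at 1.63 and FADS1 at 1.60 (median 1.10, percentile 70.5). Hypoxia and glycolysis genes were higher in 7 of 9 listed, with VEGFA at 2.05 and PDK1 at 2.03 (median 1.51, percentile 95.8). Of the growth arrest list, 5 genes were listed, 3 higher and 1 lower. CDKN2B was at -2.27, CDKN1A at 1.11 and GADD45B at 1.07, and CDKN2C went from 8.16 to 23.9 FPKM. Estrogen response genes were higher in 12 of 30 and lower in 1, PGR, with a median of 0.48 (percentile 10.3). With R5020, 749 rows were higher and 344 lower of 2043. After centring (shift 0.50) the split was 372 higher and 757 lower. The replication and progestin medians were then 2.37 and 1.05, the fatty acid median was 0.60 and the estrogen median -0.02, and the mitosis median was just under 2-fold.

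With both hormones in T47D, RBP2 (37.2 FPKM against 0.680 with vehicle), ARMC12 (4.74), AZGP1 (4.53), HSD11B2 (4.45), SEPTIN4 (4.29), TRNP1 (4.17), STC2 (4.16) and TMEM63C (4.06) were highest against vehicle. IL1R1 (-3.54), TGFB2 (-3.18), LINC01947 (-3.16), L3MBTL3 (-3.09), LINC01845 (-3.08), TWIST1 (-2.88), SPINK8 (-2.86) and ROBO2 (-2.86) were lowest. Against vehicle 816 rows were higher and 432 lower of 2051 (268 and 814 after centring, shift 0.70). All 27 listed replication genes were higher than with vehicle (median 2.69).

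Set against E2 alone, adding R5020 to T47D gave 405 higher and 216 lower rows of 1948 (295 and 302 after centring, shift 0.17), 621 in all, against 967 with all deposited rows. RBP2 (5.28), ARMC12 (4.94), NDRG1 (4.30) and PNMT (4.19), the gene of the adrenaline-forming enzyme, were highest. NCF2 (-3.44), SEMA6A (-3.12), LINC01947 (-3.02) and SUSD3 (-2.94) were lowest. Of the 30 listed estrogen response genes 10 were lower and 0 higher than with E2 alone (median -0.47, percentile 0.04). CXCL12 was lower by -2.77, PDZK1 by -2.68, PGR by -2.41 and TFF1 by -2.09. The 27 replication genes were all above 0, 18 of them past 2-fold (median 1.29), among them RRM2 (1.99), MYBL2 (1.93) and E2F2 (1.86). Progestin response genes were higher in 12 of 17 (median 1.76), with F3, the tissue factor gene, at 3.38. Fatty acid genes were higher in 7 of 9 (median 1.33, percentile 99.6). NDRG1 was 3.95 FPKM with E2 and 87.1 with both hormones, from 19.6 with vehicle.

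**Figure D1:**
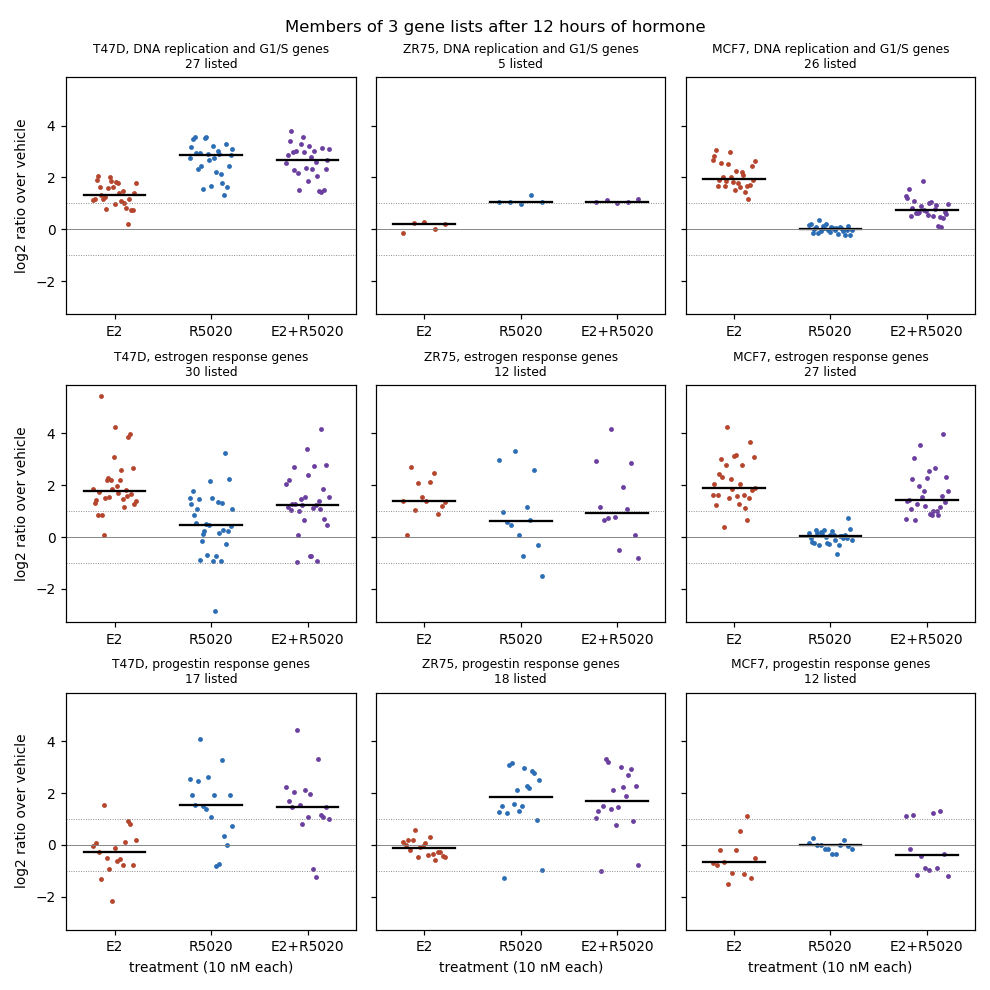
Each point is the log2 ratio over vehicle (vertical axis) of 1 listed gene of the replication, estrogen or progestin list in T47D, ZR75 or MCF7 after E2, R5020 or both (horizontal axis). Black bars are medians and dotted lines mark 2-fold. Replication genes have medians of 1.31, 2.87 and 2.69 in T47D and of 1.96, 0.02 and 0.74 in MCF7.

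In ZR75 with R5020, ARMC12 went from 1.89 to 201 FPKM (6.40) and PNMT from 7.42 to 280 (5.15), followed by FMO5 (4.36) and RBM24 (4.15). HPD (-3.05), BAMBI (-3.00), RIPOR3 (-2.89) and SOX2, a stem cell transcription factor gene (-2.88), were lowest. R5020 gave 365 higher and 301 lower rows of 1205, against 94 and 44 of 1188 with E2. Progestin response genes were higher in 15 of 18 and lower in 1 (median 1.85, percentile 100), with HSD11B2 at 3.16, F3 at 3.08, PDK4 at 2.95 and SGK1 at 2.83. The 4 listed fatty acid genes were all higher, ELOVL5 most (2.96), then ACOX1 (14.2 to 41.1 FPKM), ACSL1 (1.27) and FADS1 (1.24). Only 5 replication genes were listed, of which 4 were higher, and all 5 ratios lay between 0.99 and 1.32. Growth arrest genes were higher in 4 of 6 listed and lower in 1, BTG2 being at 1.53.

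E2 in ZR75 was highest at ELOVL2 (2.71), OLFM1 (2.48), KLK10 (2.48) and RBM24 (2.17). The lowest were the histone genes H2AC13 (-1.85) and H4C2 (-1.61), which belong to a family of near-identical copies and are uncertain, with RNF225 (-1.73) and SRARP (-1.63). Estrogen response genes were higher in 10 of 12 listed (median 1.38, percentile 100), MYC at 2.13 and GREB1, a growth regulator gene, at 2.09. Both hormones gave ARMC12 6.25, PNMT 4.76, RBM24 4.34 and GREB1 4.16, and BAMBI -3.25, GPRC5B -2.90, SOX2 -2.85 and CXCL14 -2.78, with 358 higher and 331 lower rows of 1208. Against E2 alone, both hormones gave 284 higher and 240 lower rows of 1162 (355 and 136 after centring, shift -0.19). ARMC12 (6.20), PNMT (4.63), FMO5 (4.49) and CASQ1 (4.20) were highest, and BAMBI (-2.82), SOX2 (-2.64), RIPOR3 (-2.63) and CXCL14 (-2.42) lowest. Estrogen response genes went both ways, with 4 higher and 5 lower than with E2 alone. TFF1 was -2.17 and ELOVL2 -2.05, whereas GREB1 was 2.08 and PTGES 1.99. The E2 count of 138 rows was 89 with a floor of 5, 219 by the log2 folds of the authors' deposited table and 253 with all deposited rows.

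In PR-deficient T47D cells TFF1 went from 0.683 to 8.08 FPKM with E2 (2.86), followed by RBM24 (1.94), AMZ1 (1.94) and HSPB8 (1.89). GPR19 (-2.30), CYP46A1 (-1.76), HCG14 (-1.62) and DDX3X (-1.60) were lowest. Of 10 listed estrogen response genes, 7 were higher with E2 (median 1.28, percentile 99.9), 0 with R5020 (median 0.27) and 9 with both (median 1.44). Against E2 alone, none of the 10 reached 2-fold with both hormones (0 higher, 0 lower, median 0.12), TFF1 being at -0.11. No replication or mitosis gene of the lists had a row in this table (0 listed).

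R5020 in PR-deficient T47D was highest at LY6E-DT (2.60), PAGE2 (0.99), GNG13 (0.87) and ODAD1 (0.87) and lowest at FAM168A (-2.34), HCG14 (-1.58), LINC00525 (-1.56) and CYP46A1 (-1.51), all at vehicle FPKM of 2.03 or less. It gave 14 higher and 36 lower rows of 218 (23 and 24 after centring, shift -0.16), 50 in all. That total was 29 without rows that join a small RNA, 79 by the log2 folds of the authors' deposited table and 144 with all deposited rows, which include repeated IDs. E2 gave 41 and 40 of 226 (58 and 29 after centring, shift -0.16), 81 in all, which became 124 with a pseudocount of 0.1, 133 by the log2 folds of the authors' deposited table and 166 with all deposited rows. Both hormones gave 59 and 34 of 232 (198 in all with all deposited rows), with TFF1 (2.75), AMZ1 (2.23), HSPB8 (16.3 to 66.8 FPKM) and C5AR2 (1.96) highest and FAM168A (-1.57), LINC00336 (-1.47), HCG14 (-1.42) and H4C5 (-1.37) lowest. Both against E2 gave 31 and 18 of 204, 49 in all, against 24 without rows that join a small RNA and 190 with all deposited rows. The named ends there were GPR19 (1.75), DDX3X (1.73), SERPINA6 (1.70) and DIRAS2 (1.59), and FAM168A (-2.08), UXT-AS1 (-1.24), LINC01372 (-1.09) and SMIM15-AS1 (-1.07). Of the PR-deficient rows used, 46.8% had a vehicle FPKM of 1 or more, against 75.3% in T47D.

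MCF7 cells responded to E2 with GREB1 (7.66 to 156 FPKM, 4.26), AGR2 (4.06), NPY1R (4.04) and PCP4 (3.79) highest and ACHE (-2.90), PSCA (-2.76), TM4SF1 (-2.56) and GRHL3 (-2.56) lowest. All 26 listed replication genes were higher (median 1.96, percentile 100), with CDC6 at 3.04, MCM10 at 2.97, CDC45 at 2.81 and CCNE2 at 2.67. Of 17 listed mitosis genes 16 were higher (median 1.23), and of 27 estrogen response genes 25 (median 1.88, percentile 100), TFF1 at 3.66. Apoptosis genes were lower in 4 of 6 listed (median -1.39, and -0.98 after centring, percentile 0.12), BMF at -1.96 and BBC3 at -1.25. E2 gave 418 higher and 324 lower rows of 1363 (502 and 99 after centring, shift -0.41).

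R5020 alone gave 45 higher and 45 lower rows of 1368 in MCF7, 90 in all, against 145 by the log2 folds of the authors' deposited table and 155 with all deposited rows. DMC1 (2.01), FRG1 (1.53), C8orf88 (1.40) and the histone gene H4C9 (1.32) were highest, and MORN2 (-1.68), MAD2L1BP (-1.65), SNORC (-1.62) and H2BC17 (-1.54) lowest. None of the replication, mitosis, estrogen or progestin list members reached 2-fold with R5020 (0 higher and 0 lower in each list), with medians of 0.02, -0.03, 0.03 and -0.02. The percentile of the progestin median was 65.3.

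With both hormones in MCF7, TFF1 (3.96), GREB1 (3.56), PKIB (3.27) and AGR2 (3.09) were highest against vehicle, and ATP6V0A4 (-3.01), PGM5 (-2.51), RBBP8NL (-2.43) and BMF (-2.29) lowest, with 159 higher and 301 lower rows of 1360 (245 and 148 after centring, shift -0.28). Replication genes were higher in 7 of 26 (median 0.74, and 1.02 after centring). Against E2 alone, 24 of the 26 were lower and 0 higher (median -1.25, percentile 0), TK1 at -1.77, UHRF1 at -1.64, CDC45 at -1.62 and GINS2 at -1.61. Of 17 mitosis genes 14 were lower (median -1.24, percentile 0.02), CDK1 at -1.64. Estrogen response genes were lower in 2 of 27, ELOVL2 (-1.65) and RAPGEFL1 (-1.04), with a median of -0.47 (percentile 19.0). CEP85 (2.77, from an E2 value near 0), the heme oxygenase gene HMOX1 (2.71), FOSL1 (2.41) and the cystine transporter gene SLC7A11 (2.29) were highest, and TRAPPC4 (-2.43), APOC1 (-2.25), HAUS1 (-1.95) and NUF2 (-1.94) lowest. TRAPPC4 stood out in the E2 library only, at 308 FPKM against 46.1 with vehicle, 44.9 with R5020 and 56.6 with both. The comparison held 104 higher and 239 lower rows of 1213 (198 and 110 after centring, shift -0.36). After centring, the replication median was -0.90 and the mitosis median -0.88, neither past 2-fold, and the estrogen median was -0.12.

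The design sets R5020 in the absence and presence of E2 side by side. In T47D the ratio of R5020 over vehicle and that of E2+R5020 over E2, which share no library, had a Spearman rho of 0.75 (Pearson 0.68) across 1881 rows. Of 425 rows past 2-fold in both, 411 had the same sign. The sizes were not equal: of 745 rows past 2-fold higher with R5020 alone, 326 were also past 2-fold higher on top of E2. Of 295 lower rows, 85 were also past 2-fold lower. In ZR75 rho was 0.81 (Pearson 0.78, 1129 rows), with 382 of 389 rows on the same side. There 228 of 364 higher rows and 154 of 283 lower rows were also past 2-fold on top of E2. T47D siControl, siNF1C and siFOXA1 had rho of 0.76, 0.76 and 0.76. In PR-deficient T47D rho was 0.13 across 179 rows (0.0071 with all deposited rows), with 8 of 12 rows past 2-fold in both on the same side, and in MCF7 it was -0.04 across 1196 rows, with 13 of 29. The tables list genes by their change, which shapes these correlations.

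**Figure D2:**
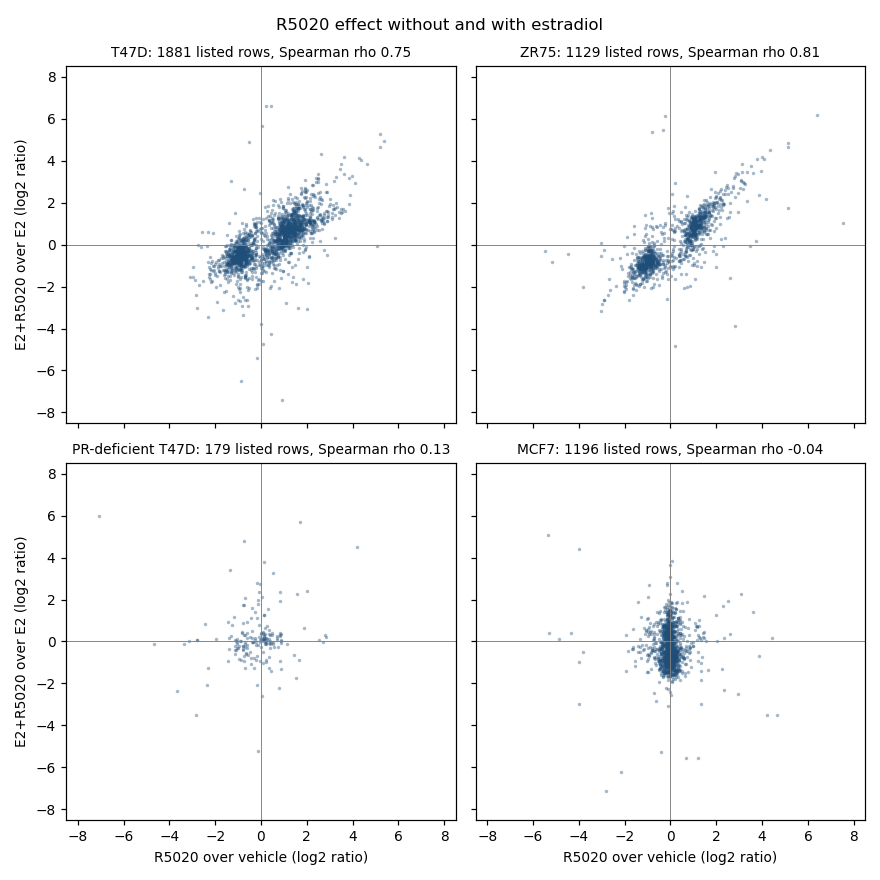
Each point is 1 listed row that passed the floor, with its log2 ratio of R5020 over vehicle on the horizontal axis and of E2+R5020 over E2 on the vertical axis, in 4 models. Ratios on both axes rise together in T47D (rho 0.75) and ZR75 (rho 0.81), where rho describes rank order and not equal size. They spread along the vertical axis in MCF7 (rho -0.04).

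T47D siControl cells, a separate set of 4 libraries, had the highest rank correlations with parental T47D among the 6 other models. E2 was highest at CXCL12 (3.96), OLFM1 (3.32), SERPINA6 (3.18) and STC2 (2.76) and lowest at the histone gene H4C3 (-2.51), CAPS2 (-1.77), HERC3 (-1.69) and MNX1 (-1.65), with 127 higher and 61 lower rows of 1016 (199 and 27 after centring, shift -0.20). The total of 188 was 125 with a floor of 5 and 324 by the log2 folds of the authors' deposited table. R5020 was highest at HSD11B2 (3.99), TMEM63C (3.82), TRNP1 (3.58) and AQP3 (3.44) and lowest at NPHP1 (-3.43), CAPS2 (-2.26), IL1R1 (-2.12) and ADGRL2 (-1.81), with 270 and 150 of 1028. The NPHP1 ratio rests on the R5020 library, at 0.691 FPKM against 12.4 with vehicle, 6.68 with E2 and 8.40 with both. Both hormones gave 353 and 247 of 1034 (229 and 348 after centring, shift 0.20), TMEM63C (4.58), HSD11B2 (4.51), CLIC6 (3.94) and AQP3 (3.50) at one end and H4C3 (-2.91), CBLN2 (-2.45), IL1R1 (-2.40) and KCNJ3 (-2.27) at the other. Both against E2 gave 199 and 94 of 956, from TMEM63C (4.98), SLC25A18 (3.94), AQP3 (3.65) and CLDN8 (3.27) to PGR (-2.49), CXCL12 (-2.41), RIPOR3 (-2.00) and SEMA6A (-1.92). Of 22 listed replication genes, 0 were higher with E2 (median 0.53) and 22 with R5020 (median 1.46, percentile 100).

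Parental T47D and siControl shared genes beyond the overlap of independent lists. Across 627 genes listed in both, E2 ratios had a rho of 0.89. There were 85 genes higher in both where independent lists would share 27.6, and 13 lower in both where they would share 3.30. Across 642 genes R5020 ratios had a rho of 0.90, with 202 higher in both (independent 97.2) and 72 lower in both (independent 20.1). The SD of the difference between both sets of libraries was 0.55 log2 units for E2 and 0.70 for R5020, the nearest measure here of the spread between experiments. CXCL12, OLFM1, SERPINA6, STC2, NKAIN1 (3.06 and 2.58) and THBS1 (2.67 and 2.49) led the shared E2 genes. HSD11B2, TMEM63C, TRNP1, SLC25A18 (3.48 and 3.02), PLLP (3.86 and 2.76) and KCNG1 (3.63 and 2.76) led those of R5020. H4C3 was furthest apart for both hormones (1.33 and -2.51 with E2, 2.18 and -1.81 with R5020). RRM2, at 3.27 in T47D and 1.04 in siControl with R5020, and FAM111B, at 3.65 and 1.52, were also among the 6 furthest apart. L3MBTL3, the lowest named gene with R5020 in T47D, was among them as well, at -3.09 in T47D and -0.64 in siControl. For E2, NDRG1 was among the 6 furthest apart, at -2.18 in T47D and -0.38 in siControl. The lower values of L3MBTL3 with R5020 and of NDRG1 with E2 were thus not repeated at 2-fold in siControl.

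In T47D siNF1C cells, R5020 was highest at AZGP1 (3.93), SLC25A18 (3.83), S100P (3.73) and TMEM63C (3.52) and lowest at CDH13 (-2.62), IL1R1 (-2.04), FUT8 (-1.83) and HEPHL1 (-1.79), with 225 higher and 103 lower rows of 747 (106 and 253 after centring, shift 0.42). E2 was highest at CXCL12 (3.05), OLFM1 (2.63), SUSD3 (2.36) and SERPINA6 (2.35) and lowest at CDH13 (-3.07), DMC1 (-2.00), F8 (-1.43) and SIRT4 (-1.32), with 55 and 23 of 729, 78 in all, against 131 by the log2 folds of the authors' deposited table and 135 with all deposited rows. Both hormones gave 276 and 121 of 746 (101 and 288 after centring, shift 0.63), AZGP1 (4.21), HSD11B2 (4.06), SLC25A18 (3.92) and PNMT (3.79) being highest and IL1R1 (-2.32), PMCH (-2.24), CBLN2 (-2.14) and SOX2 (-2.01) lowest. Both against E2 gave 214 and 64 of 706 (136 and 179 after centring, shift 0.35), with AZGP1 (3.81), CDK12 (3.76), SLC25A18 (3.68) and PNMT (3.65) highest and PMCH (-2.47), PGR (-2.34), CXCL12 (-2.15) and CCDC170 (-2.01) lowest. The CDK12 ratio rests on 1 library, with 22.5 FPKM with vehicle, 18.1 with E2, 19.3 with R5020 and 251 with both. PMCH stood apart in the same library, at 0.000325 FPKM against 1.87 with vehicle, 2.27 with E2 and 1.59 with R5020. The CDH13 ratios over vehicle all use the vehicle library, at 64.0 FPKM against 7.15 with E2, 9.99 with R5020 and 27.0 with both. Replication genes had medians of 0.10 with E2 and 1.04 with R5020 (0.62 after centring) over 22 listed, 0 and 14 of them being higher. For 146 genes past 2-fold with E2 in parental T47D, the median of the siNF1C ratio over the siControl ratio was 0.573. In absolute size 123 genes had the smaller ratio in siNF1C, and 19 of the 146 had opposite signs in the 2 sets. The median absolute E2 ratio of these genes was 0.541 in siNF1C and 0.857 in siControl. For 299 genes past 2-fold with R5020 the median was 0.888, and for 316 genes past 2-fold with both hormones it was 0.908.

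In T47D siFOXA1 cells, FKBP5 went from 11.8 to 285 FPKM with R5020 (4.54), followed by NOP56 (3.04), AZGP1 (2.62) and SLC25A18 (2.52), and F8 (-2.87), CBLN2 (-2.04), NDUFAF5 (-1.71) and SOX2 (-1.68) were lowest, with 93 higher and 30 lower rows of 318 (58 and 73 after centring, shift 0.23). The total of 123 was 188 by the log2 folds of the authors' deposited table. NOP56 was at 38.3 FPKM with vehicle, 145 with E2, 318 with R5020 and 66.7 with both. Its R5020 ratio was therefore not repeated with both hormones (0.79 over vehicle). E2 was highest at CCNYL1 (6.47), ZC3H12A (6.32), SERPINA6 (11.6 to 96.1 FPKM) and TFF1 (2.98) and lowest at HEATR6 (-3.80), F8 (-2.16), DMC1 (-1.86) and PHC2 (-1.82), with 49 and 12 of 320, 61 in all, against 97 by the log2 folds of the authors' deposited table. The rows of this table carry 1 accession each, so a small RNA joined to such a row would not show. Both hormones gave 109 and 47 of 319 (59 and 110 after centring, shift 0.45), with FKBP5 (4.70), SLC25A18 (2.97), AZGP1 (2.87) and RUNX1 (2.60) highest and HEATR6 (-4.02), F8 (-2.55), CBLN2 (-2.51) and IQCH (-2.38) lowest. Both against E2 gave 92 and 35 of 302, from FKBP5 (4.28), SLC25A18 (3.12), AZGP1 (2.96) and TMEM63C (2.80) to CCNYL1 (-6.45), ZC3H12A (-6.32), PGR (-2.67) and CXCL12 (-2.62). CCNYL1 was at 245 FPKM with E2 and at most 2.71 in the other libraries of this set, and ZC3H12A at 697 and at most 8.93. Their extreme ratios in both comparisons therefore rest on the E2 library. The F8 ratios over vehicle all use the vehicle library, at 21.1 FPKM against 4.31 with E2, 2.44 with R5020 and 3.19 with both. Estrogen response genes were higher with E2 in 16 of 18 listed (median 1.43, percentile 100). Relative to siControl, the median ratio was 0.780 for E2 (77 genes), 0.820 for R5020 (139 genes) and 0.80 for both hormones (148 genes) among genes past 2-fold in parental T47D.

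Between cell lines, R5020 ratios of ZR75 followed those of T47D across 402 genes listed in both (rho 0.69). There were 115 genes higher in both (independent 64.0) and 45 lower in both (independent 19.8), led by ARMC12, PNMT, TMEM63C, KCNG1, HSD11B2 and STAT5A (3.29 in T47D and 2.79 in ZR75). SDC2 was -2.03 in T47D and 2.24 in ZR75, SEMA6A -1.66 and 2.09, and PEG10 0.67 and 4.07. E2 ratios of the same pair had a rho of 0.54 over 379 genes, with 32 higher in both (independent 8.82) and 1 lower in both (independent 0.929). OLFM1, KLK10 (2.18 and 2.48), RBM24 (2.44 and 2.17) and MYC (3.07 and 2.13) were higher in both. TFF1 was 3.96 in T47D and 1.36 in ZR75.

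E2 ratios of MCF7 followed those of T47D as well (rho 0.70, 480 genes), with 102 genes higher in both (independent 67.2) and 29 lower in both (independent 8.53), such as TFF1, CXCL12 (5.46 and 2.42), IFITM10 (3.59 and 2.27), IGFBP4 (2.29 and 2.26) and MYB (2.18 and 3.12). R5020 ratios did not (rho 0.08, 488 genes): 265 of the 488 were higher in T47D and 5 in MCF7, with 1 higher in both (independent 2.72). TMEM63C was 4.28 in T47D and -0.07 in MCF7, ATAD2 3.99 and 0.18, and CDC6 3.56 and -0.16. In PR-deficient T47D, E2 ratios had a rho of 0.53 with those of T47D over 60 genes and 15 genes were higher in both (independent 8.53), TFF1 (3.96 and 2.86), HSPB8 (2.21 and 1.89) and MYC (3.07 and 1.46) among them. R5020 ratios had a rho of -0.04 over 53 genes and 0 genes were past 2-fold in the same direction (independent 0.528 higher and 0.377 lower). CLDN8 was 2.85 in T47D and -0.38 in PR-deficient cells, and MYC 2.15 and -0.26. The rho of -0.04 was -0.36 with a floor of 5 and 0.08 with none.

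E2 and R5020 ratios were positively correlated across listed genes in T47D cells, but the overlap of higher genes exceeded that of independent lists in only 1 of the pairings below. Rows are listed by their change, which shapes the correlations and the independent overlaps. To avoid a common vehicle library, E2 ratios of parental T47D were set against R5020 ratios of siControl (rho 0.43, 626 genes). Of 187 genes higher with E2 and 204 higher with R5020, 73 were shared (independent 60.9), and 19 were lower with both (independent 10.5). In the reverse pairing (R5020 in parental T47D and E2 in siControl, rho 0.44, 632 genes), 31 genes were higher with both where independent lists would share 36.0, and 15 lower with both (independent 7.21). Genes past 2-fold higher with E2 in siControl and used from parental T47D (90) had there a median of 1.70 with E2, 0.43 with R5020 and 1.16 with both. Of these, 34 were lower and 5 higher with both hormones than with E2 alone, with a median of -0.52. In the reverse direction, 194 genes chosen in T47D had in siControl a median of 0.27 for both against E2, 22 being lower and 29 higher.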

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

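The tests of weaker estradiol action, of scaling and of lower NFIC were chosen after the results were seen, and the others were set down before their values were computed. None of the differences between models that open this part was tested, because each group has 1 library.

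With R5020, SDC2 was -2.03 in T47D and 2.24 in ZR75, and SEMA6A was -1.66 and 2.09. CYP1B1 was 2.22 in T47D and -1.31 in ZR75, and KRT23 was 1.66 and -1.74. A second T47D row of KRT23, with lower mean FPKM, was at 0.84, which is under 2-fold. With E2, RHOBTB1 was -1.72 in T47D and 2.28 in MCF7, and RIPOR3 was 1.46 and -1.29. H4C3, 1 of a family of near-identical histone genes, was 1.33 in T47D and -1.12 in PR-deficient T47D with E2 and -2.51 in T47D siControl, and with R5020 it was 2.18 in T47D and -1.81 in siControl. DMC1, a meiotic recombinase gene, was 1.54 with E2 in T47D, -2.00 in siNF1C and -1.86 in siFOXA1, and with R5020 it was 3.83, -1.37 and -1.28. The knockdown values of DMC1 lay near the floor. FPKM with vehicle, E2 and R5020 were 1.85, 0.0882 and 0.407 in siNF1C and 2.03, 0.198 and 0.539 in siFOXA1. The median of the replication and G1/S genes for both hormones against E2 was 1.29 in T47D and -1.25 in MCF7 (1.12 and -0.90 after centring, so that MCF7 was then within 2-fold). These values were singled out because the models lay on opposite sides of no change, each by at least 2-fold, among the 6 genes furthest apart in each pair. Over all genes listed in both tables, 10 of 402 lay so for ZR75 with R5020 and 2 of 379 with E2. MCF7 had 7 of 480 with E2 and 2 of 488 with R5020, PR-deficient T47D 3 of 60 with E2 and 3 of 53 with R5020, and each siRNA set 1 gene per hormone.

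For the replication genes of MCF7, lower with both hormones than with E2 alone, a scaling difference between libraries is argued against, since their median lay -0.977 from that of all listed genes, although it was within 2-fold after centring (-0.90). For progestin receptor action that needs estradiol, the rho with the R5020 ratios of ZR75 was 0.0152 over 232 genes, meeting the bound against it. That test cannot decide, because ZR75 lists few of the replication genes. With the R5020 ratios of T47D the rho was -0.58 over 529 genes, and the progestin list had a median of 0.41. Weaker estradiol action in that culture cannot be told apart, because the estrogen response genes had a median of -0.474, between the bounds of the test, and the upper bound was moved from -0.5 to -0.25 after this value was seen. Across 529 genes the rho of the same MCF7 ratios with the E2 ratios of T47D was -0.45, the direction weaker estradiol action would give. That relation was also seen before it was weighed, and it cannot decide. The rho with the R5020 ratios of T47D was further from 0, and the MCF7 E2 library enters both the ratio and the selection of listed rows. With 1 culture, a biological difference of MCF7 stays open and untested, and so does any other difference of the culture given both hormones. Of the 4 named genes highest there against E2, HMOX1 was at 1.09 over vehicle, FOSL1 at 2.35, SLC7A11 at 1.13 and CEP85 at 0.45.

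Rows that join a small RNA with another gene held extreme ratios, 12 of 52 past 4 log2 units in T47D against 15 of 2411 other rows. Small RNA reads counted into the joined row may be the source: the R5020 ratios of joined rows had a rho of 0.0561 between T47D and siControl (19 rows), and those of single-gene rows 0.901 (726 rows). No biological explanation was tested.

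E2 ratios were smaller in siNF1C than in siControl, with a median of 0.573 of the siControl ratio. The siFOXA1 E2 ratios were 0.780 of those of siControl, which met the bound for a loss shared by both knockdown sets. That test cannot decide, because siFOXA1 has a target of its own and separate effects of both siRNAs would look the same. The siFOXA1 medians for R5020 (0.820) and both hormones (0.80) were similar, so the reduction there was not particular to E2. Both E2 medians divide by the same siControl libraries, over different genes (146 and 77). A difference of the siControl libraries therefore cannot be told apart from a shared loss. An overall compression in siNF1C cannot be told apart, because its R5020 median of 0.888 lay between the bounds of the test. The siNF1C median for both hormones was 0.908, but no bound had been set for it, so it cannot decide. In absolute size, 197 of 299 genes had the smaller ratio in siNF1C with R5020, and 212 of 316 with both hormones. Lower NFIC, at 0.651 of siControl, cannot be told apart either. Its test asked for siFOXA1 ratios that were not reduced, and they were smaller. As siFOXA1 is not a neutral control, that result does not decide about NFIC. The condition on siFOXA1 was added to the NFIC test after the values were seen.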

How the results depend on the processing

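Of 280 count values under alternative settings 259 stayed within 1.5 times the main count and 21 did not, 164 of 171 correlations stayed within 0.1 and 7 did not. Of the gene ratios and list medians past 2-fold, 0 changed sign. A pseudocount cannot change the sign of a ratio, and the largest centring shift was 0.70, so those settings could not reverse them. Leaving out rows that join a small RNA could not move them either, because they come from single-gene rows. Ratios of named genes moved by 0.25 log2 units or more in 509 of 1984 values, 149 of 248 with the authors' log2 folds, 136 of 248 with a pseudocount of 0.1, 130 of 248 with a pseudocount of 1 and 88 of 248 after centring. List medians moved that far in 82 of 1216 values, 61 of them after centring. With random lists matched in 5 bins, 3 of 152 list percentiles moved by 5 or more. The alternatives added after seeing the data were the vehicle value of each run, all rows with an ID listed once, all deposited rows, the authors' log2 folds, and leaving out rows that join a small RNA. The cause of the shifts below was not tested. With a pseudocount of 0.1, 124 rows were past 2-fold with E2 in PR-deficient T47D (main 81). Without a floor, the R5020 rho of PR-deficient T47D with T47D was 0.0754 (main -0.0393), and with a floor of 5 it was -0.356 and the E2 rho 0.413 (main 0.533). The floor of 5 gave 89 rows with E2 in ZR75 (main 138) and 125 in siControl (main 188). With all deposited rows, repeated combinations included, T47D had 967 rows for both hormones against E2 (main 621), ZR75 253 with E2 (main 138), MCF7 155 with R5020 (main 90) and siNF1C 135 with E2 (main 78). PR-deficient T47D then had 166 with E2, 144 with R5020, 198 with both and 190 for both against E2 (main 81, 50, 93 and 49). The rho between R5020 without and with E2 was then 0.598 in T47D (main 0.749), 0.682 in ZR75 (main 0.807), 0.0071 in PR-deficient T47D (main 0.130) and 0.659 in siNF1C (main 0.764). By the authors' log2 folds, E2 gave 219 rows in ZR75 (main 138), 133 in PR-deficient T47D (main 81), 324 in siControl (main 188), 131 in siNF1C (main 78) and 97 in siFOXA1 (main 61), and R5020 gave 79 in PR-deficient T47D (main 50), 145 in MCF7 (main 90) and 188 in siFOXA1 (main 123). Without rows that join a small RNA, PR-deficient T47D had 29 rows with R5020 (main 50) and 24 for both against E2 (main 49). A stricter authors' q-value, other count tests and leaving out a replicate were not run, because the tables hold no q-values, counts or replicates. By replicate number, no paired analysis was possible because the groups share fewer than 2 numbers. Pairing the treatments within each model, with the model as a block, was not run, because the tables were normalized separately and list genes by their change. Depth is unknown, so what it limits cannot be given.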

Other observations

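Some members of other lists were higher in MCF7 with both hormones than with E2 alone. Of 6 listed apoptosis genes 3 were higher and 0 lower (median 0.93, percentile 99.9), with BBC3 at 1.65, PMAIP1 at 1.16 and FAS at 1.12. Most of the listed apoptosis genes were lower with E2 than with vehicle, so these ratios do not show a rise over vehicle. BMF was at -0.33 against E2 and at -2.29 against vehicle with both hormones. Of 4 listed immediate-early genes 2 were higher, ATF3 (1.87) and KLF6 (1.42). Of 4 listed mesenchymal transition genes 3 were higher, SERPINE1 (1.40), CCN2 (1.40) and SNAI1 (1.35). Lists of 4 genes were given no percentile. With R5020 alone, 0 members of these lists were past 2-fold in MCF7.

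In T47D, androgen response genes were lower with E2 in 3 of 5 listed (median -1.41, percentile 0.015), TRPM8 at -1.52 and TMPRSS2 at -1.41. With R5020, HOMER2 was at 2.12 and TMPRSS2 at -1.18. AR, the androgen receptor gene, was at -1.28 with R5020. Interferon response genes went both ways with R5020, 3 of 9 higher and 2 lower, ISG20 at 1.48 and OAS2 at -1.47.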
